A study of Homo sapiens with 6 samples.

How the data were processed

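RNA of KG1a cells was measured on 6 one-colour Agilent arrays, 3 of unirradiated cells and 3 of cells given 8 Gy, all 48 h after treatment. Per the labels' protocols, the cells grew in IMDM with serum, RNA was extracted with a column kit and checked for purity and integrity, and it was reverse transcribed, amplified in vitro and labelled with the dye Cy3. Groups were taken from the treatment, source name and description in the labels. Titles of the irradiated samples carry 0Gy as well as 8Gy, which is a conflict within the labels.

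The arrays were scanned and read with Agilent Feature Extraction 11.5.1.1, per the file headers, which also name hg19 as the genome build of the design. The deposited spot intensity used is, per the file headers, background-subtracted and detrended within the array, with substitute values for dim spots, and was not normalized between arrays. Mean pixel intensity of the spot and median intensity of its local background, both uncorrected per the file headers, served for an alternative. Flags for being well above background, saturated or an outlier came from the same files.

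A second, deposited table holds log2 values with 1 row per probe. Its scale and centring are not stated in the sources used here. Set against the scanner files, it matched log2 intensities scaled to the 75th percentile of each array and centred per probe on the median of the control arrays, with a median absolute difference of 0.0022. The match was 0.0718 with the mean of the controls and 0.278 with the median of all arrays. Its column medians were 0, 0 and 0 for the controls and −0.23, −0.24 and −0.20 for the irradiated samples. Its direction thus followed from the scanner values, and it was used as an alternative only.

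Each array had 62976 spots and 58717 outside the controls. Outlier-flagged spots were dropped, the log2 values of a probe's spots were averaged, and 21 of 50599 probes were left out because every spot was flagged on an array. The log2 of each probe was taken relative to the 75th percentile of its array. A probe was kept where it was well above background on all 3 arrays of at least 1 group, which left 26791. A gene was represented by its brightest kept probe. Of 4683 genes with more than 1 kept probe, 1858 had a probe in the opposite direction, and among the 2151 of these that were called 663 did.

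Accessions of 28159 probes matched the RefSeq gene table of the assembly GRCh38.p14, 3236 more were named by symbol, and 19183 kept the name in the file. Since that assembly is not the one of the array design, the table gave names and the span of genes only, and no coordinates. Coordinates are those of the probes in the files.

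Differences between the groups were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. A second count required a change of at least 2-fold. With 36 lists of genes fixed before the data were examined, camera tested whether the list's genes shifted more than the others, with a preset correlation of 0.01 and adjustment over the 36 lists. Camera with an estimated correlation and fry were alternatives. The lists held 987 memberships, of which 978 were on the array and 831 were measured, and those not measured are not analysed here. Where a gene was well above background on all arrays of one group and none of the other, its fold is a bound. It sets the bright group's mean against, per dim array, the higher of the gene's own value and the lowest signal that was well above background, and a bound under 1-fold is not given.

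The genes named were set by a rule fixed before the data were examined. It took the 15 largest increases and the 15 largest decreases among called genes with a symbol that were above background on all 6 arrays and whose groups did not overlap. It added the 3 highest bounds per direction (none was lower), up to 4 members of each list with the smallest p, and CDKN1A, MDM2, GDF15, FAS, CD34, GAPDH, ACTB, B2M and TBP. A few genes that the rule took are not reported here, and counts of named genes over the alternatives leave them out.

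On simulated data of 20445 genes with 3 samples per group, made from the real spread, the fit recovered 47.6% of genes changed 2-fold and 13.9% of genes changed 1.5-fold. Of its calls 5.73% were false and 0 had the wrong direction. A list shifted by 0.5 on the log2 scale was found in 100% of 20 runs. For genes, only 200 were changed per run, against 10534 called in the data. Spreads were shuffled over genes and genes were drawn independently, so these rates need not hold for the data.

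Alternatives were normexp background correction with an offset of 50, quantile, median and spike-in scaling (to the mean of the 7 E1A control probes above background on all arrays), no filter on dim probes, a filter for signal on all 6 arrays, and the mean of a gene's probes. Others were a trended and robust variance, array weights, the deposited table, the replicate number as a block, probes in place of genes, a test against 1.5-fold, and each array left out in turn. For named genes and lists, changes under normexp, median and spike-in scaling were shifted so that the median of all genes equalled the main one. The adjusted p of named genes was taken after that shift. Counts of genes and shares of directions were not shifted. Removal of each array's trend with brightness and probe GC content, and with gene span as well, was added after the data were seen. Natural splines with 4 degrees of freedom per term were fitted to each array's deviation from the gene's mean over the arrays. Slide could not be fitted as a block because each group lay on 1 slide of its own. For arrays, precision is limited by their number, and spots of a probe differed with an SD of 0.098 to 0.138 within an array. Figures were drawn with matplotlib 3.10.9.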

Results

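KG1a is an established human acute myeloid leukaemia cell line whose cells carry the progenitor marker CD34. Its cells received 8 Gy of gamma radiation from a cobalt source or were left unirradiated (0 Gy). Their RNA was measured 48 h later on one-colour Agilent arrays, with 3 arrays per group. The comparison asks which transcripts stood at another level in the irradiated cells at that time. The titles of the irradiated samples also carry 0Gy, whereas their treatment, source name and description give 8 Gy, which was followed. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

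Each array held 62976 spots, and no spot outside the controls was saturated. On the control arrays 21550, 22115 and 22997 probes were well above background, and on the irradiated arrays 28857, 27904 and 29570 were, of 50578 analysed. Over genes above background on all 6 arrays, the irradiated arrays correlated with each other at 0.996 to 0.997, control replicates 1 and 2 at 0.996, and control replicate 3 with these at 0.991 and 0.992. Correlations between the groups ran from 0.973 to 0.979. All 3 control arrays lay on one slide and all 3 irradiated arrays on another, scanned separately, so slide and dose cannot be told apart. The number of arrays limits the precision of every value.

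In irradiated KG1a cells, of 28 measured replication-dependent histone genes, which supply the proteins that wrap newly made DNA, 26 fell and 0 rose, by a median of −1.56 on the log2 scale. Of 35 DNA replication and S phase genes 24 fell and 0 rose, among them CCNE1, the cyclin that drives entry into S phase, which was 2.45-fold lower. Both lists were lower than the other genes by camera with its preset correlation but not with an estimated one (adjusted p = 0.253 for histones and 0.213 for S phase), and the S phase median of −0.47 was −0.23 after removal of a trend with brightness and GC content. PSAT1 and ASNS, enzymes of serine and asparagine synthesis, were 2.67-fold and 2.59-fold higher, and CTSG, a protease of granulocyte precursors, was 4.52-fold higher (n = 3 arrays per group for each). Direct targets of p53 went both ways, 5 higher and 11 lower of 30 measured.

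All values are log2 signals relative to the 75th percentile of the same array, and changes are irradiated minus control. Of 20445 genes tested with limma, 10534 passed an adjusted p of 0.05, with 5684 higher and 4850 lower in irradiated cells. A change of at least 2-fold was met by 4065 genes, 3764 higher and 301 lower. The irradiated and control values did not overlap for 13267 genes (64.9%). Interchangeable arrays would give 10% for a gene not selected by group. That is no measure of chance here, as genes were kept through the arrays of a group and slide and dose coincide. The split of directions moved with the scaling, with the filter on dim probes and with trend removal. Higher genes made up 54% of the calls here, 35.8% after normexp background correction, 20% after median scaling and 99.8% after scaling to the spike-in probes, which left the median of all genes at −0.10, −0.65 and 1.15, against 0.02 here. At 2-fold the shares were 92.6% here, then 70.7%, 27.5% and 99.8% in that order, and normexp left 375 genes. Under the main scaling, higher genes made up 37.7% of the calls with no filter on dim probes. They made up 34% with signal required on every array and 47% after removal of the brightness and GC trend. At 2-fold, 4240 genes rose and 4232 fell with no filter. With signal on every array 873 rose and 293 fell, and after trend removal 1272 rose and 907 fell. The 75th percentile used for scaling was 159.6, 161.5 and 122.7 on the control arrays and 238.9, 218.6 and 249.3 on the irradiated arrays. Scaling to it thus lowered irradiated values relative to control values. Median probe signals ran from 6.78 to 8.29 on control arrays and from 17.99 to 21.42 on irradiated arrays. Against these, normexp added an offset of 50, which draws changes of dim genes toward 0. Under normexp, median and spike-in scaling, values of named genes and lists below are given after a shift to the main median of all genes.

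The changes also went with how bright a gene was, in a way that depended on the filter on dim probes. The median log2 change ran from 1.39 in the dimmest quintile of genes through 0.38, −0.05 and −0.19 to −0.27 in the brightest, and 56.8% of the dimmest genes but 0.807% of the brightest were 2-fold higher. Among genes above background on all 6 arrays it ran from 0.13 in the dimmest quintile to −0.28 in the brightest, and without a filter the dimmest quintile of all genes stood at −1. Of the 3764 genes at least 2-fold higher, 858 were well above background on all 6 arrays, against 290 of the 301 lower ones. A total of 2880 genes were above background on all irradiated arrays and on no control array, and 2 showed the opposite. Those 2, the locus LOC100507420 and the transcript THC2503633, were named after their values were seen. Requiring signal on all 6 arrays left 1166 genes at 2-fold. Control spots for ERCC sequences, which are synthetic, were above background on 3.839%, 2.768% and 3.393% of spots on control arrays and on 14.345%, 11.488% and 16.696% on irradiated arrays. Of human probes as bright as the ERCC probes, 3.9% to 4.8% were above background on control arrays and 13% to 17.6% on irradiated arrays.

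**Figure D1:**
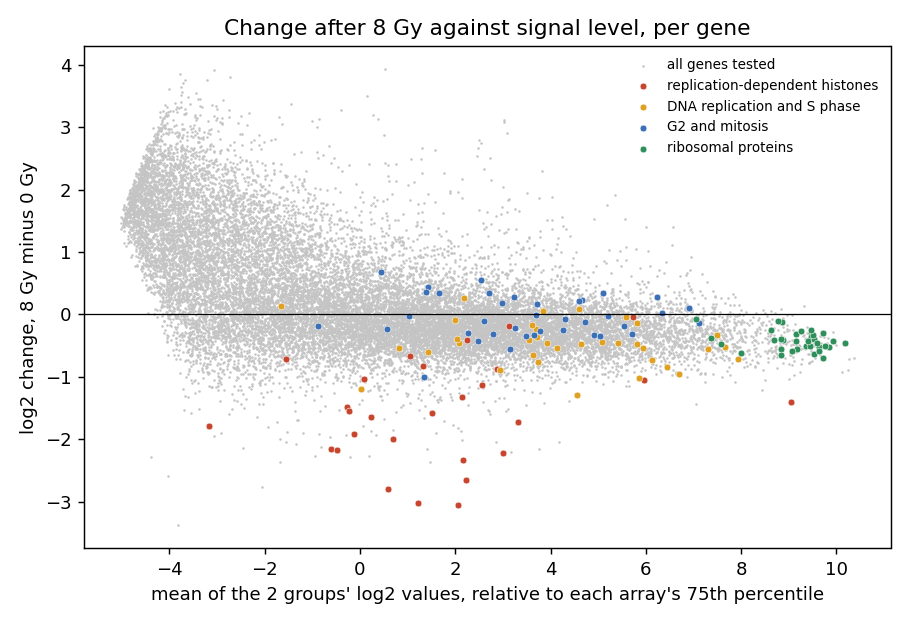
Each point is a gene. The horizontal axis gives the mean of both groups' log2 values relative to the array's 75th percentile, the vertical axis the log2 change of 8 Gy minus 0 Gy, and colours mark 4 gene lists over all 20445 genes in grey. Dim genes at the left lie mostly above 0, with a median of 1.39 in the dimmest quintile (0.13 among genes above background on all 6 arrays, −1 without a filter on dim probes), replication histones lie far below it at a median of −1.56, and ribosomal proteins sit at the bright end at −0.43, which became 0.03 under quantile normalization.

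Of 36 gene lists fixed in advance, 14 differed from the other genes by camera with its preset correlation, all lower, and each lay lower on all 3 irradiated arrays than on any control array. Those other genes included the dim ones that rose (median 1.39 in the dimmest quintile), and 4 lists passed with signal required on all 6 arrays. Of all genes tested 27.8% were called higher and 23.7% lower, and counts within lists are to be read against these shares. None of the 14 passed when camera estimated the correlation from these 6 arrays, where the lowest adjusted p was 0.213 and 8 lists had an unadjusted p under 0.05. Removing each array's trend with brightness and probe GC content, an alternative chosen after the data were seen, left the histone and S phase lists lower and raised the unfolded protein response and ATF4 list past the threshold. The fry test of each list on its own called 32 lists, 8 higher and 24 lower. It does not compare a list with other genes. Spike-in scaling, in which control replicate 3 stood apart with a spike-in mean of 13.1 on the log2 scale against 12.2 to 12.5 on the others, ended the calls of 102 named genes.

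The replication-dependent histones fell by a mean of 1.56 on the log2 scale, with the 3 irradiated arrays at −1.49, −1.57 and −1.62 and the controls at −0.13, −0.13 and 0.26 around their mean. In the list, 26 genes fell (26 adjusted over the list alone; camera adjusted p = 1.93e-11, adjusted p = 0.253 with an estimated correlation). Over all alternatives that adjusted p lay between 2.18e-21 and 0.253. The 15 deepest falls among named genes measured on all arrays were all histones. The linker histone gene H1-3 went from 3.57 ± 0.57 to 0.53 ± 0.15 (SD, n = 3), 8.26-fold lower (limma adjusted p = 0.000826). Its probe lies on chromosome 6 from 26234699 to 26234758 (hg19). The linker histone genes H1-4 (chromosome 6, 26156928 to 26156987) and H1-5 (27834629 to 27834688) were 8.08-fold and 6.99-fold lower. H2BC7, H3C2, H2AC20, H4C5, H2AC13, H4C9, H2AC17, H2AC12, H2AC4, H2AC15, H3C15 and H2AC11 followed at 6.82-fold to 4.47-fold lower, and H2BC4 was 2.78-fold lower. Histone genes are near copies of each other, so a value for any one of them is uncertain. Probe positions here are those of the array design, and exon or UTR annotation of that build was not used here.

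S phase and replication genes fell on all 3 irradiated arrays, to means of −0.51, −0.46 and −0.47 against −0.04, −0.01 and 0.05 in the controls. The list had 24 lower members (24 adjusted over the list alone; median −0.47; camera adjusted p = 9.85e-07, adjusted p = 0.213 with an estimated correlation, and 3.1e-07 to 0.213 over the alternatives). CCNE1 (chromosome 19, 30315106 to 30315165) fell from 5.21 ± 0.07 to 3.91 ± 0.03 (SD, n = 3; limma adjusted p = 0.000325). The helicase subunits MCM7, MCM2 and MCM5, which unwind DNA at origins, changed by −0.96 ± 0.09, −0.84 ± 0.09 and −1.02 ± 0.12 (SE). After removal of the brightness and GC trend the list's median was −0.23 (adjusted p = 0.0184).

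Genes of G2 and mitosis did not pass as a group. Of 38 measured, 8 rose and 10 fell (7 and 9 adjusted over the list alone; median −0.09; camera adjusted p = 0.388), and its adjusted p ran from 0.0202 to 0.894 over the alternatives. It passed as lower under median scaling, and as higher under normexp (median 0.17) and once gene span was added to the removed trend (0.18). MKI67, the proliferation marker, fell from 1.84 ± 0.22 to 0.84 ± 0.13 (SD, n = 3; limma adjusted p = 0.00273; chromosome 10, 129913193 to 129913252). CENPE, a kinetochore motor, fell by 0.55 (a call lost under normexp, −0.23), and ECT2, needed for cytokinesis, rose by 0.68. CENPA, the centromere histone, rose by 0.28 (limma adjusted p = 0.0178), a call lost without any of the irradiated replicates 1, 2 and 3 (0.0594, 0.0654 and 0.0683; 0.000574 to 0.768 over the alternatives). That of ECT2 was lost without irradiated replicate 2 (0.0639) or 3 (0.0507), with 0.00405 to 0.336 over the alternatives.

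**Figure D2:**
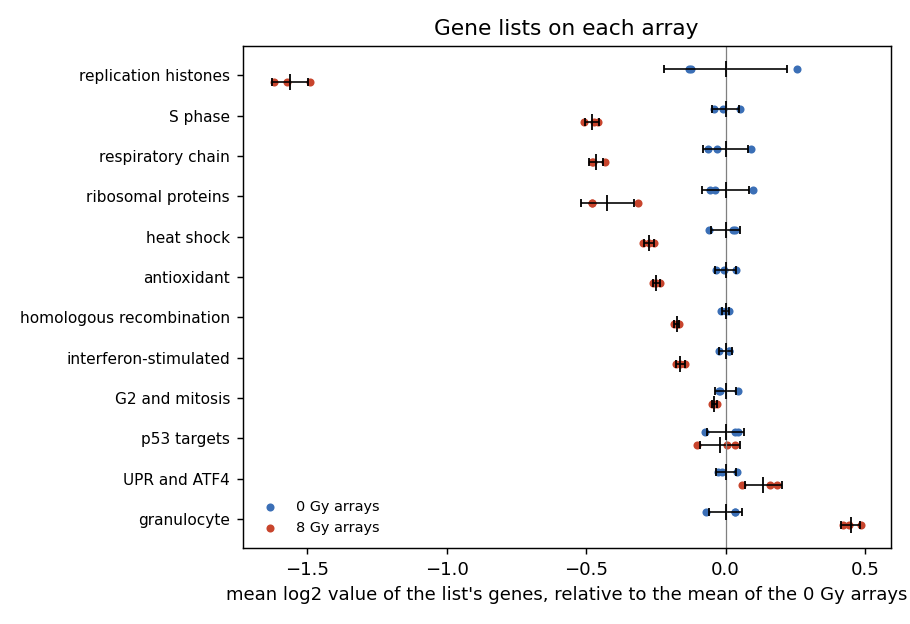
Mean log2 value of each list's genes on each array, relative to the mean of the 0 Gy arrays. Dots are arrays, ticks the group means and bars 1 SD of 3 arrays. Histones lie at −1.49 to −1.62 and S phase genes at −0.46 to −0.51 after 8 Gy, while G2 and mitosis genes lie at −0.03 to −0.05. List medians became 0.07 for homologous recombination and 0.03 for interferon genes under normexp, after a shift to the main median of all genes. The median of ribosomal proteins became 0.03 under quantile normalization.

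The p53 target list had a median of 0.00 and did not pass (5 higher and 11 lower, the same counts adjusted over the list alone; camera adjusted p = 0.347). CDKN1A, the cell cycle inhibitor, fell by 1.05 ± 0.30 (SE; limma adjusted p = 0.029; chromosome 6, 36652178 to 36652237). Its probe was dim, at −3.02 on control and −4.07 on irradiated arrays, and was above background on 2 of 3 control arrays, so its call is uncertain. That call was lost without control replicate 2 (0.0589), irradiated replicate 1 (0.09) or irradiated replicate 3 (0.084), and under spike-in scaling, with 0.00251 to 0.09 over the alternatives. MDM2, the p53 antagonist, rose by 1.16 ± 0.28 (SE; limma adjusted p = 0.0161; chromosome 12, 69233570 to 69233629), with 3 of its 4 probes in that direction. Its call was lost without irradiated replicate 2 (log2 1.08, adjusted p = 0.0597, and 0.00125 to 0.0597 over the alternatives). PLK2, a stress-responsive kinase, rose from −0.16 ± 0.17 to 0.84 ± 0.20 (SD, n = 3), whereas RRM2B, a ribonucleotide reductase subunit, and RPS27L and FDXR fell by 0.52, 0.50 and 0.61. The call of RPS27L was lost under normexp (−0.16) and trend removal (−0.24). FAS, the death receptor, fell by 0.42 (limma adjusted p = 0.0136) with 2 of 3 probes in that direction, a call lost without irradiated replicate 1 (0.0509) or 3 (0.0549), with 0.00809 to 0.628 over the alternatives. GDF15, a secreted stress cytokine, did not pass (log2 0.05, limma adjusted p = 0.694) and stood at −0.38 (0.0474, and up to 0.969 over the alternatives) once the brightness and GC trend was removed.

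Base excision, nucleotide excision and mismatch repair had 17 of 32 members lower and 2 higher (17 and 2 adjusted over the list alone; median −0.36; camera adjusted p = 0.00566, and 0.213 as adjusted p with an estimated correlation). PMS2, MSH3 and MSH6 of mismatch repair fell by 0.80, 0.66 and 0.55, and the glycosylase gene NEIL1, above background on 2 of 3 control arrays, rose by 1.27. Homologous recombination and Fanconi genes had 9 of 32 lower and 1 higher (8 and 1 adjusted over the list alone), with a median of −0.19 that became 0.07 under normexp after the shift (camera adjusted p = 0.0296, adjusted p = 0.213 with an estimated correlation). In it RAD51C and RAD51D, paralogs of the strand exchange protein, fell by 0.89 and 0.91, FANCI by 0.71 and RAD50 by 0.54. Checkpoint genes had 6 of 19 lower and 0 higher (6 and 0 adjusted over the list alone; median −0.25; camera adjusted p = 0.029, adjusted p = 0.26 with an estimated correlation). RAD9A fell by 0.80 and ATM, the kinase that senses double-strand breaks, by 0.44, but 2 of its 3 probes went the other way and their mean gave 0.23 (limma adjusted p = 0.0832, and 0.00395 to 0.609 over the alternatives). End joining did not pass (2 higher and 6 lower of 16, 2 and 7 adjusted over the list alone; median −0.22; camera adjusted p = 0.324), with XRCC6 lower by 0.70 and LIG4 at least 4.09-fold higher. The call of XRCC6 was lost under quantile normalization (−0.27) and trend removal (−0.32). Over the alternatives the adjusted p of the 3 lists that passed ran from 0.00199 to 0.989, and none passed under normexp, quantile normalization, either other filter or trend removal, nor the checkpoint list under spike-in scaling.

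Of 32 respiratory chain and ATP synthase genes 23 fell and 0 rose (24 and 0 adjusted over the list alone; median −0.51; camera adjusted p = 9.85e-07, adjusted p = 0.214 with an estimated correlation), including UQCRC1 by 0.78 and ATP5F1D by 0.83. Of 36 cytosolic ribosomal protein genes 27 fell and 0 rose (30 and 0 adjusted over the list alone; camera adjusted p = 4.94e-07, adjusted p = 0.382 with an estimated correlation), with a median of −0.43 that became 0.03 under quantile normalization. RPS16, RPL3 and RPS19 fell by 0.69, 0.58 and 0.59, calls that were lost under quantile normalization. Ribosome biogenesis and MYC target genes had 13 of 31 lower and 0 higher (13 and 0 adjusted over the list alone; camera adjusted p = 0.00177, adjusted p = 0.213 with an estimated correlation). Their median of −0.25 became 0.04 under normexp after the shift and 0.00 under quantile normalization. ODC1, which starts polyamine synthesis, fell by 0.67. Glycolysis and hypoxia genes had 12 of 28 lower and 4 higher (12 and 5 adjusted over the list alone; median −0.34; camera adjusted p = 0.0331, adjusted p = 0.213 with an estimated correlation), with LDHA, ENO1 and PGAM1 lower by 0.80, 0.67 and 0.74. The biogenesis and glycolysis lists did not pass under normexp, quantile normalization or either other filter. Over the alternatives the 4 lists' adjusted p ran from 1.34e-08 to 0.929. These genes are bright, and none of the 4 lists passed after removal of the brightness and GC trend, where the respiratory list stood at a median of −0.18 (0.0985) and the ribosomal one at −0.05 (0.696).

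Heat shock genes had 8 of 15 lower and 0 higher (8 and 0 adjusted over the list alone; median −0.31; camera adjusted p = 0.0162, adjusted p = 0.213 with an estimated correlation), with the chaperones HSPA8 and HSPA4 lower by 0.94 and 0.67. Lysosome and autophagy genes had 15 of 29 lower and 2 higher (17 and 2 adjusted over the list alone; median −0.32; camera adjusted p = 0.00125, adjusted p = 0.213 with an estimated correlation), with the protease gene CTSD lower by 0.73. In the NRF2 and antioxidant list 13 of 24 fell and 3 rose (13 and 3 adjusted over the list alone; median −0.40; camera adjusted p = 0.0103, adjusted p = 0.213 with an estimated correlation). There FTL, the ferritin light chain, was 2.11-fold lower, while SLC7A11, the cystine transporter (chromosome 4, 139085433 to 139085492), rose 2.06-fold and GPX2 was at least 2.34-fold higher, a call lost under normexp. Over the alternatives the adjusted p of these 3 lists ran from 0.000964 to 0.473, and none passed under normexp, quantile normalization, either other filter or trend removal, nor the heat shock and NRF2 lists under median scaling and the former under spike-in scaling.

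The unfolded protein response and ATF4 list had 8 of 26 members higher and 4 lower (8 and 4 adjusted over the list alone; camera adjusted p = 0.833). Its median was −0.03 and its mean 0.14, and camera gave the direction of the mean. It passed as higher under normexp (median 0.25, adjusted p = 0.00793) and after trend removal (0.32, 0.0293), with 0.00793 to 0.992 over the alternatives. PSAT1, an enzyme of serine synthesis (chromosome 9, 80944778 to 80944837), went from 3.55 ± 0.18 to 4.97 ± 0.02 (SD, n = 3; limma adjusted p = 0.000501). ASNS, asparagine synthetase (chromosome 7, 97481461 to 97481520), rose by 1.37 ± 0.12 (SE; limma adjusted p = 0.000657). CHAC1, which degrades glutathione, rose by 0.83, and SEL1L, part of the machinery that removes misfolded proteins, by 1.07 with 1 of its 2 probes in that direction.

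Markers of blood cell maturation were mixed. CTSG (chromosome 14, 25042788 to 25042847) went from 1.05 ± 0.18 to 3.23 ± 0.10 (SD, n = 3; limma adjusted p = 0.000283). CSF3R, the receptor of the granulocyte growth factor, rose by 0.71 and CEBPA, a myeloid transcription factor, by 0.47, while PRG2, the eosinophil basic protein, fell by 0.96. The granulocyte list did not pass (4 higher and 1 lower of 10, 5 and 1 adjusted over the list alone; median 0.46, or 0.24 with 2 genes at their bounds; camera adjusted p = 0.298). The monocyte and macrophage list had 8 of 15 higher and 2 lower (8 and 2 adjusted over the list alone; median 0.66; camera adjusted p = 0.0974), and passed without control replicate 1 (0.0372, and up to 0.869 over the alternatives). With each array left out in turn the list had a median of 0.431 to 0.86. Of its members 4 were above background on irradiated arrays alone, and with these at their bounds the median was 0.19. ITGAM, a myeloid integrin, rose by 0.88, and CD80 and FCN1 were at least 1.01-fold and 1.24-fold higher, though CD80 stood at −0.00 under normexp, where the call of FCN1 was lost too. Without a filter on dim probes the medians were −0.33 for the granulocyte and −0.12 for the monocyte list, and ERCC control spots were above background on up to 16.696% of spots after 8 Gy. In the stem and progenitor list 2 of 23 rose and 7 fell (1 and 5 adjusted over the list alone; median −0.07, and −0.182 to −0.046 with each array left out in turn; camera adjusted p = 0.288). CD34 did not pass (log2 −0.31 ± 0.16 SE, limma adjusted p = 0.155) but did without control replicate 3 (−0.49, 0.00635, and up to 0.819 over the alternatives).

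**Figure D3:**
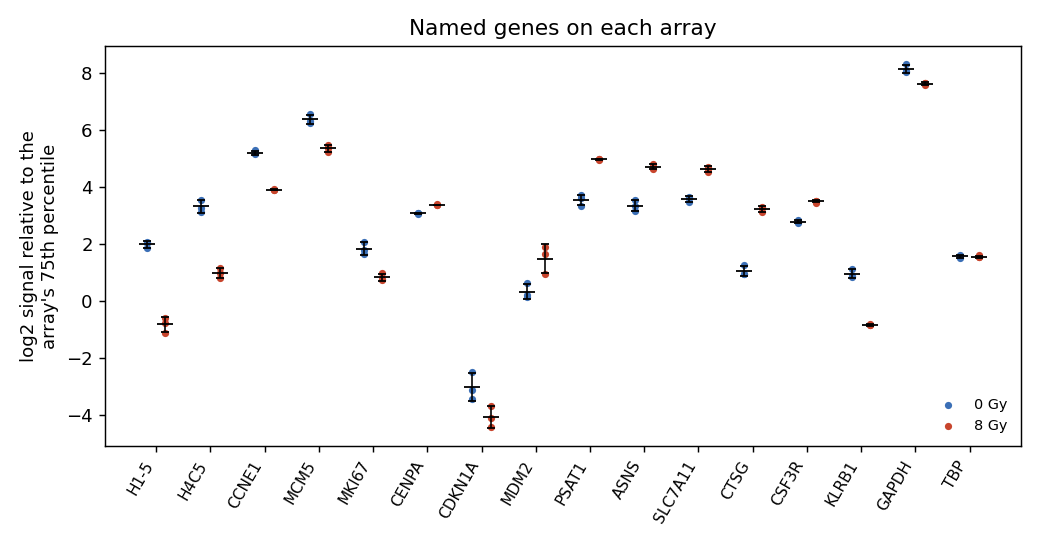
Log2 signal of 16 genes on each array, relative to the array's 75th percentile. Dots are arrays, ticks the group means and bars 1 SD of 3 arrays. H1-5 and CCNE1 lie lower after 8 Gy and PSAT1, ASNS and CTSG higher, with no overlap of the arrays, while TBP lies at 1.57 and 1.56 in the groups.

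Interferon-stimulated genes had 11 of 41 members lower and 3 higher (10 and 3 adjusted over the list alone; camera adjusted p = 0.0221, adjusted p = 0.214 with an estimated correlation), with a median of −0.18 that became 0.03 under normexp after the shift. MX1, RSAD2 and OAS3, antiviral effectors, fell by 0.95, 0.89 and 0.60, and XAF1 rose by 1.05. TGF-beta pathway genes had 8 of 20 lower and 2 higher (8 and 2 adjusted over the list alone; median −0.25; camera adjusted p = 0.0361, adjusted p = 0.214 with an estimated correlation), and missed the threshold without control replicate 3 (0.0644). In it SKIL and SMAD7, feedback inhibitors of the pathway, were 2.85-fold and 2.09-fold lower. Over the alternatives the adjusted p of these 2 lists ran from 0.00773 to 0.817, and neither passed under normexp, quantile normalization, either other filter or trend removal.

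The largest increases among named genes measured on all 6 arrays were of NACA4P and TPT1P8, which are pseudogenes, and GOLGA6C, NEURL1, CSNK1A1L, JDP2, KRTAP5-2, ASRGL1, UGT2B10, SPRR2F, HLA-DQB1, GPAT2, KRTAP6-2, SLC6A9 and CTSG. They ran from 15.3-fold for NACA4P to 4.52-fold for CTSG. Keratin-associated proteins (KRTAP5-2, KRTAP6-2), SPRR2F and UGT2B10 are known from hair, skin and liver. NACA4P went from −1.44 ± 1.08 to 2.50 ± 0.08 (SD, n = 3), with control replicate 3 apart from its group. Its log2 change of 3.94 was 3.32 without that array. Pseudogenes and members of gene families such as GOLGA6C share sequence with other genes, so their values are uncertain. JDP2, a repressor of AP-1 genes, rose from −0.45 ± 0.35 to 1.96 ± 0.10 (SD, n = 3; limma adjusted p = 0.000475; chromosome 14, 75937082 to 75937141). Among genes not well above background on any control array, KRTAP10-2, SLC2A8 and MIAT had the highest bounds, at least 5.49-fold, 4.59-fold and 4.58-fold higher. Many of these genes were dim, and ERCC control spots were above background more often on irradiated arrays too (up to 16.696%, against at most 3.839%).

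Housekeeping genes differed among themselves. TBP, a general transcription factor, was at −0.00 ± 0.08 (SE; limma adjusted p = 0.971) and at 0.22, 0.13 and 0.13 under normexp, quantile normalization and trend removal. GAPDH fell by 0.51 (limma adjusted p = 0.00902), a call lost under normexp (−0.21), quantile normalization (−0.17) and trend removal (−0.20). ACTB fell by 0.42 (limma adjusted p = 0.0357) with 1 of its 2 probes in that direction and stood at 0.07 under quantile normalization, and its call was lost without control replicate 1 (0.0509), 2 (0.0701) or 3 (0.0739) or irradiated replicate 1 (0.112) or 3 (0.118), with 0.0143 to 0.703 over the alternatives. Normexp, no filter, the mean of its probes and trend removal ended it too. B2M was at −0.02 (limma adjusted p = 0.882) and at 0.28, 0.34 and 0.35 under normexp, quantile normalization and trend removal.

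Pro-apoptotic genes had 3 higher and 8 lower of 23 (3 and 8 adjusted over the list alone; median −0.03; camera adjusted p = 0.394), with BMF 2.22-fold lower, and survival genes 0 higher and 4 lower of 17 (0 and 3 adjusted over the list alone; median −0.14; camera adjusted p = 0.27), with AKT2 lower by 0.97. NF-kB and inflammatory genes had 4 higher and 9 lower of 23 (4 and 9 adjusted over the list alone; median −0.19; camera adjusted p = 0.33). CD83 fell by 0.58 there (a call lost under normexp), and IL6 was not well above background on any control array and gave no bound above 1-fold. Senescence and secreted factors had 3 higher and 4 lower of 16 (2 and 4 adjusted over the list alone; median −0.09; camera adjusted p = 0.324), with CSF2 2.31-fold lower and CSF1 2.26-fold higher. Immediate early genes had 5 higher and 2 lower of 22 (4 and 2 adjusted over the list alone; median 0.02, or 0.00 with 3 genes at their bounds; camera adjusted p = 0.631), with DUSP5 higher by 0.57 (a call lost under normexp) and JUND lower by 0.67. Sterol synthesis had 3 higher and 4 lower of 23 (2 and 4 adjusted over the list alone; median −0.08; camera adjusted p = 0.388), with PMVK lower by 0.51. Drug efflux had 1 higher and 1 lower of 10 (0 and 1 adjusted over the list alone; median 0.19, or 0.14 with 1 gene at its bound; camera adjusted p = 0.71), with ABCA2 lower by 0.67, a call lost with the mean of its probes.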

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

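Each test below except the splits of the arrays was chosen only after the result was seen. ERCC control spots, which no comparison used, were well above background on 14.345%, 11.488% and 16.696% of spots on the irradiated arrays and on at most 3.839% on a control array. The median ERCC spot minus its local background showed no clear rise, at −0.95, −0.60 and −1.39 on control and −1.69, −0.55 and −0.44 on irradiated arrays. For spots outside the controls that median was 12.48, 10.98 and 8.02 on control and 20.7, 21.4 and 25.1 on irradiated arrays. Whether ERCC RNA was added is not given in the sources used here.

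The rise of dim genes had a median log2 change of 1.39 in the dimmest quintile of the genes kept, and of 0.13 in that of genes above background on all 6 arrays. On irradiated arrays left out of the filter and the ranking in turn, the median was 1.295, 1.316 and 1.418 (intervals from 1.26 to 1.448). Chance brightness of the array left out is thus argued against, but selection in a wider sense stays open. Genes were still kept through the other irradiated arrays. They were also ranked as dim partly by the control values that were then subtracted, which favours a rise. Unspecific signal stays open: the 9 ERCC probes kept in that brightness range had a median change of 1.172 (95% bootstrap interval 0.935 to 1.694), but all 9 met the filter on irradiated arrays only, which fixed the sign, and without the filter all 96 stood at a median of −0.899 and human probes of like brightness at −0.848. Earlier forms of the filter test gave −0.562 for 65 dim genes above background on all arrays and −1 (interval −1.004 to −0.996) without the filter; both met the side that blames labelling or the filter, but were set aside because the choice of genes, or the floor, fixed the sign. A difference between the slides cannot be told apart from dose, as 0 slides held both groups, and an effect of dose itself stays open.

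Replication histone and S phase genes fell. For histones a trend with brightness and probe GC content is argued against, as the median after its removal was −1.584 (quartiles −2.251 and −0.931, adjusted p = 7.01e-12, and 2.18e-21 to 0.253 over the alternatives) against −1.56 before. For S phase genes most of the fall went with that trend, from −0.471 (quartiles −0.682 and −0.282) to −0.226, which met the side of the test that names the trend. The trend as the whole cause is argued against at camera's preset correlation only. There the list still passed (quartiles −0.486 and −0.105, camera adjusted p = 0.0184, and 3.1e-07 to 0.213 over the alternatives). The value of 0.213 came with an estimated correlation before trend removal, and that form was not run after it. Fewer cells in any phase cannot be decided. G2 and mitosis genes stood at a mean of −0.04 and lay 0.199 (95% bootstrap interval over genes 0.079 to 0.322) above −0.24, the bound set from the S phase mean of −0.479. They thus fell less than S phase genes, the side against fewer cells. But the bound moves with the scaling. The list passed as lower under median scaling (camera adjusted p = 0.0202) and as higher under normexp (0.0468). In it 8 genes rose and 10 fell, among the latter the proliferation marker MKI67 (−0.997). An effect of dose and a slide difference stay open for the rest, as untested.

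Ribosomal protein and respiratory chain genes fell as well. A trend with brightness and probe GC content may account for most of this. The ribosomal median went from −0.428 (quartiles −0.528 and −0.325) to −0.045 (−0.16 and 0.071, adjusted p = 0.696), and to −0.035 (0.817) with gene span added, with 1.34e-08 to 0.844 over the alternatives. The respiratory median went from −0.508 (quartiles −0.649 and −0.275) to −0.184 (−0.37 and 0.019, adjusted p = 0.0985) and −0.153 (0.0943), with 4.6e-07 to 0.214 over the alternatives. Both calls ended as the shift itself shrank, and an effect of dose or slide stays open.

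Of the 10 splits of the 6 arrays, 1 gave as many genes as the real one (10534, highest other 0), 1 as many 2-fold genes (4065, highest other 0) and 1 as many lists (14, highest other 11). At an unadjusted p under 0.05 limma gave 12035 genes in the real split and at most 409 in another. The real split is also that of the slides, and the splits are too few for a share under 0.05. The other splits mix doses and slides within their groups, which widens the spread there, so their counts are no measure of chance.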

How the results depend on the processing

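Trend removal was added only after the data were seen. Leaving out 1 array gave 7590 to 11210 genes, 3670 to 4268 at 2-fold and 13 to 15 lists. With no filter 15859 genes passed. At 2-fold there were 375 genes under normexp, 6947 under median scaling, 12345 under spike-in scaling, 8472 with no filter, 1166 above background on all 6 arrays and 2179 after removal of the brightness and GC trend. Lists numbered 6 under normexp, 3 under quantile normalization, 4 with no filter and 4 above background on all 6 arrays. They numbered 3 after removal of the brightness and GC trend, 5 with span added, 32 by fry and 0 by camera with an estimated correlation (8 at an unadjusted p under 0.05). The replicate block gave 8115 genes, 3983 at 2-fold and 14 lists, and 9 named genes were not called under it. Deviations of same-numbered arrays correlated at −0.014, −0.061 and −0.055 and no array correlated best with its own number. Pairing by number was thus not seen, but deviations from means of 3 arrays cannot exclude it. Slide as a block was not run, since each slide held 1 group. Signal over background limits dim genes, with 42.6% to 45.5% of probes above it on control and 55.2% to 58.5% on irradiated arrays.

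Over all alternatives the named genes kept direction and side of the threshold 2825 times, lost a call 239 times, gained one 10 times and changed sign 37 times, of which 18 were called in neither setting. The lists did so 581, 78, 3 and 58 times, 46 of these called in neither. Under normexp, median and spike-in scaling, direction was counted after the shift to the main median of all genes. Before that shift, 99.8% of all calls were higher under spike-in scaling and 20% under median scaling. Of the lost gene calls 102 came under spike-in scaling, 34 under normexp and 27 after trend removal. The cause of the changes below was not tested.

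Values under normexp are given after the shift of its median of all genes from −0.104 to 0.018. Those just above 0 may owe their sign to that shift. Under normexp the sign turned for ABCG2 (−0.244), AKT1 (0.082), ALDH3A1 (−0.028), B2M (0.284), CD80 (−0.004), GDF15 (−0.115), IL6 (−0.067), KLF4 (−0.029), KRT18 (0.073), MS4A1 (−0.07), NR4A2 (−0.146) and TBP (0.218). It also turned for the lists of B cells (−0.084), G2 and mitosis (0.166), antigen presentation (0.202), apoptosis (0.176), homologous recombination (0.07), interferon (0.029), p53 targets (0.014), ribosome biogenesis (0.038), stem cells (0.011), sterol synthesis (0.191), survival (0.085) and ATF4 (0.252). Under quantile normalization it turned for ABCG2 (−0.082), ACTB (0.066), B2M (0.337), GDF15 (−0.261) and TBP (0.131). So did the lists of G2 and mitosis (0.124), antigen presentation (0.289), apoptosis (0.148), Notch (0.016), ribosomal proteins (0.029), ribosome biogenesis (0.001), sterol synthesis (0.109), survival (0.051) and ATF4 (0.28).

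After removal of the brightness and GC trend the sign turned for ABCG2 (−0.893), ALDH3A1 (−0.133), B2M (0.35), GDF15 (−0.384), IL6 (−0.251), MS4A1 (−0.15), NR4A2 (−0.048) and TBP (0.129). So did the lists of B cells (−0.167), G2 and mitosis (0.143), NKG2D ligands (−0.04), antigen presentation (0.232), apoptosis (0.145), drug efflux (−0.012), sterol synthesis (0.141), survival (0.053) and ATF4 (0.316). With span added it turned for the lists of B cells (−0.203), G2 and mitosis (0.183), antigen presentation (0.273), apoptosis (0.109), p53 targets (0.02), ribosome biogenesis (0.006), sterol synthesis (0.101), survival (0.107) and ATF4 (0.284). With the mean of a gene's probes it turned for ABCB1 (−0.119), ATM (0.227), CD2 (0.119), KRT18 (0.293) and the lists of adhesion (−0.11), antigen presentation (0.015) and p53 targets (0.071). With no filter it turned for adhesion (−0.265), granulocytes (−0.331) and monocytes (−0.121), above background on all 6 arrays for immediate early genes (−0.018), and with array weights for TBP (0.003) and apoptosis (0.024). With each array left out in turn the values crossed 0 for B2M (−0.047 to 0.013), GDF15 (−0.011 to 0.099) and TBP (−0.033 to 0.016). They did so for the lists of antigen presentation (−0.036 to 0.041), apoptosis (−0.037 to 0.01), Notch (−0.123 to 0.062), p53 targets (−0.068 to 0.018), stroma (−0.198 to 0.019) and ATF4 (−0.082 to 0.056).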

Other observations

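The tests on parts of lists and on gene span were chosen only after the result was seen. Among markers of other blood cells, T and NK cell genes had 5 of 19 higher and 9 lower (6 and 10 adjusted over the list alone; median −0.32; camera adjusted p = 0.201). KLRB1, a lectin receptor of NK cells, was 3.45-fold lower (limma adjusted p = 0.000297), and CD2, an adhesion receptor, fell by 1.90 with 1 of its 2 probes in that direction and stood at 0.12 as the mean of both. B cell genes had 7 of 12 higher and 1 lower (7 and 1 adjusted over the list alone; median 0.54; camera adjusted p = 0.103). Of these 5 were above background on irradiated arrays alone, and with them at their bounds the median was 0.09. DNTT, the polymerase of antigen receptor joining, was at least 1.25-fold higher, a call lost under normexp. MS4A1, a B cell surface protein, gave no bound above 1-fold and turned to −0.07 under normexp, where the list's median was −0.08. ERCC control spots were above background on up to 16.696% of spots after 8 Gy, against at most 3.839%. Erythroid and megakaryocyte genes had 9 of 18 higher and 3 lower (9 and 3 adjusted over the list alone; median 0.42, or 0.40 at bounds; camera adjusted p = 0.114), and passed with the mean of a gene's probes (0.045, and up to 0.321 over the alternatives). HBG1, a fetal globin gene, rose by 0.93 and TFRC, the transferrin receptor, fell by 0.51, a call lost under normexp and trend removal. Stroma and epithelium genes had 1 of 7 higher and 1 lower (1 and 1 adjusted over the list alone; median −0.03; camera adjusted p = 0.497), namely COL5A1 by 1.09 (lost under normexp and trend removal) and PECAM1 by −0.91.

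Adhesion and homing genes had 8 of 22 higher and 8 lower (8 and 8 adjusted over the list alone; camera adjusted p = 0.757), with a median of 0.08 and a mean of 0.04 where camera gave the lower direction. CCR7, a homing receptor, fell by 2.07, and CXCL12 and CCR2 were 2.68-fold and 2.78-fold higher. Ligands of NKG2D and immune checkpoints had 4 of 17 higher and 2 lower (4 and 2 adjusted over the list alone; median 0.12, or 0.06 at bounds; camera adjusted p = 0.479). ULBP1, a stress ligand, was 2.68-fold higher and CD47 fell by 0.53, a call lost under normexp and trend removal. Notch, Wnt and Hedgehog genes had 3 of 22 higher and 6 lower (3 and 6 adjusted over the list alone; median −0.05, mean 0.04; camera adjusted p = 0.473), with JAG2, a Notch ligand, 3.30-fold lower. Antigen presentation genes had 6 of 20 higher and 3 lower (5 and 2 adjusted over the list alone; median −0.01, mean 0.25; camera adjusted p = 0.744), and passed as higher only once gene span was added to the removed trend (0.27, adjusted p = 0.037, and up to 0.946 over the alternatives). HLA-DQB1 and HLA-DPA1 were 4.72-fold and 2.47-fold higher and TAPBP, which loads class I molecules, fell by 0.59. HLA genes share sequence with each other, so their values are uncertain.

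Class II genes may have moved apart from class I genes, as a hypothesis. Their mean changes differed by 0.999 (0.977 to 1.036 over the irradiated arrays; 7 against 13 genes, exact two-sided permutation p = 0.00417). The permutation takes genes as independent, though HLA genes share sequence, and was chosen after their values were seen, so its p cannot decide the hypothesis. Of the 7 class II genes 6 lay below the array's 75th percentile in both groups and HLA-DRB1 (log2 change 0.55) above it, their mean ran from −0.49 to 0.49 over the control arrays, and with the brightness and GC trend removed the class II median went from 0.58 to 0.53 and the class I median from −0.06 to 0.23, so brightness stays open for part of the difference. For ATF4 targets against chaperones the difference was 0.427 (0.351 to 0.53 over the irradiated arrays; 12 against 11 genes, permutation p = 0.096), which leaves that hypothesis undecided. Across 12544 genes, which are not independent replicates, the trend-corrected change correlated weakly with gene span (Spearman 0.105, from 0.103 to 0.105 over the irradiated arrays), just above the bound of 0.1 set after an uncorrected correlation had been seen. The trend-corrected median change was −0.20 for genes under 5 kb and −0.02 for those over 100 kb, and −0.28 and −0.10 without the correction.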
